A study of Bifidobacterium breve UCC2003 with 4 samples.

How the data were processed

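Bifidobacterium breve UCC2003, a gut bacterium, was grown anaerobically by the authors in modified MRS medium with 0.05% cysteine and 0.5% of either ribose or N-acetylglucosamine-6-sulfate (GlcNAc-6-S), to an optical density of 0.5, per the labels' protocols. Labelled cDNA from 2 RNAs, one in Cy3 and one in Cy5, was hybridised to each Agilent array. The deposited scanner files give spot intensity, that is the mean brightness of each spot and the median brightness around it in each channel, with no correction applied, per the file headers. They also give processed intensity values, background-subtracted and dye-normalised with a lowess curve by Agilent Feature Extraction, per the file headers. The log10 ratio of red over green in each deposited file was made from those processed values by the same software, per the file headers. The version of that software is 9.5 per the submitters' processing notes and 9.1.1.1 per the file headers. The authors' series matrix holds log10 ratios in 4 columns, which were checked against the scanner files and differed from each array's own log10 ratio by at most 0.00494, so its scale and direction were settled. The median of each of these columns was 0. The authors tested genes with a regularised t-type test, Cyber-T, and took a gene as changed at p under 0.001 with a ratio over 3 or under 0.33, per the series' design text.

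Each array carried 10807 spots, of which 544 were control spots. The other 10263 spots held 5664 probes for 1888 features, with 3 probes for each feature. The features were 1843 locus tags beginning with Bbr, 20 tRNA features, 1 feature for 16S rRNA, 7 spike features, 15 plasmid features, 1 insertion element and 1 feature named only CDS. The last 4 kinds, 24 features, were left out of the gene tests. The table of gene names supplied with the data describes another strain, and 0 of the 1843 locus tags matched it. The files do not pair the tags with gene names either, so genes are reported by locus tag, and none of the 22 gene lists fixed before the data were examined, which search gene names, had a member on the array. The locus tag of atsR2 is not given in the sources used here, so its own signal could not be used to check the mutant.

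Background was corrected with normexp and an offset of 50 on the mean and local background signals, control spots were given no weight, and each array was normalised by loess, in limma 3.58.1 under R 4.3.3. Spots marked by the scanner software as outliers, between 0.224% and 4.09% of spots per array, were left out. Spots of one probe were averaged, and the median over the probes of a feature was taken. Features measured on all arrays numbered 1859, and 5 were lost to outlier spots. The 4 arrays were fitted in 1 limma model (lmFit and eBayes) with 1 coefficient for each comparison, each array entering with the sign given by its dyes, and two-sided p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The model had 2 residual degrees of freedom and a prior of 13.3. Standard deviations are over the 2 arrays of a comparison. On simulated data for the 1859 features with 200 of them changed, the fit recovered 100% of features changed by 0.5, 1 or 2 on the log2 scale in either comparison. The false share among calls was 2.91% in the simulated GlcNAc-6-S comparison and 5.66% in the simulated mutant comparison. The simulated noise was drawn independently for each feature from the fit's own spread, at the level of normalised ratios. It holds no correlation of neighbouring genes and no shift of dim features, so these shares need not hold for the real calls.

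The labels do not say whether the arrays of a comparison came from separate cultures or from the same extracts, so the p-values measure only the spread between arrays, which may be technical, and the number of arrays limits the precision. Each comparison lay on a slide and a scan of its own. A comparison is made within each array, but slide and comparison cannot be told apart where levels are set across them. Where every probe of a gene failed the scanner software's test for being well above background on both arrays in the channels of 1 RNA, its fold is a lower bound, written "at least". The bound sets the mean of the brighter RNA against the mean, per array, of the lowest signal among probes well above background or the gene's own signal if higher, from log2 values per channel after loess and Aquantile scaling. The header's multiplier for that test was 13, and no spot was saturated.

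The rule for named genes was fixed before the data were examined: in each direction, the genes with the largest log2 ratio among those past the threshold with the same sign on both arrays. Because tags could not be paired with names, it was limited to the 2 largest in each direction per comparison, and the genes the rule would have taken by annotation could not be found. The tRNA features, the runs of neighbouring tags, the change along the tag numbers and the turned sign of the GlcNAc-6-S comparison were chosen after the data were seen. A run was taken as 3 or more consecutive tag numbers changed at least 2-fold in 1 direction at an adjusted p under the threshold. Gene orders were permuted 1000 times for runs and 10000 times for the correlation of neighbours. The change along the tags was fitted as 1 cosine wave over tags changed less than 2-fold, and tested by permuting blocks of 10 neighbouring tags 1000 times; the fit recovered a wave planted in simulated data. The alternatives set before the data were examined were no background correction, normexp with an offset of 0, Agilent's processed signals, the series matrix, median centring, Aquantile scaling, the mean over probes, a fit per probe with 50% of a gene's probes required, a filter on dim probes, outlier spots kept, a dye term, each comparison fitted alone, Cyber-T with a window of 101 genes and a confidence of 10, the slide as a block, and each array left out.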

Results

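Gene expression in B. breve UCC2003 was measured on 4 two-colour arrays that form 2 comparisons of 2 arrays each, and within each comparison the dyes were swapped between the arrays. The first comparison set the wild type grown on GlcNAc-6-S, a sulfated amino sugar that also occurs in mucin glycans, against the wild type grown on ribose. The second set a mutant in atsR2 against the wild type, both on ribose. The study was on a gene cluster for a glycosulfatase, an enzyme that removes sulfate from sugars, and atsR2 is known as a regulator of such a cluster. In the first comparison the RNA labelled ribose gave the dimmer signal in both dyes: its median spot brightness was 296 in Cy3 and 233 in Cy5, which was 1.74 and 1.81 times the median of the 79 negative control spots. The RNA labelled GlcNAc-6-S gave 513 in Cy5 and 526 in Cy3, or 3.70 and 3.69 times the negative controls. In the second comparison the ratios to the negative controls lay between 1.58 and 2.06. Over the 1859 features tested, the swapped arrays correlated with r = 0.950 in the first comparison and r = 0.779 in the second once turned the same way, with Spearman's rho of 0.918 and 0.472, and 87.7% and 62.9% of features had the same sign on both arrays. These correlations are across genes, which are not independent replicates.

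**Figure D1:**
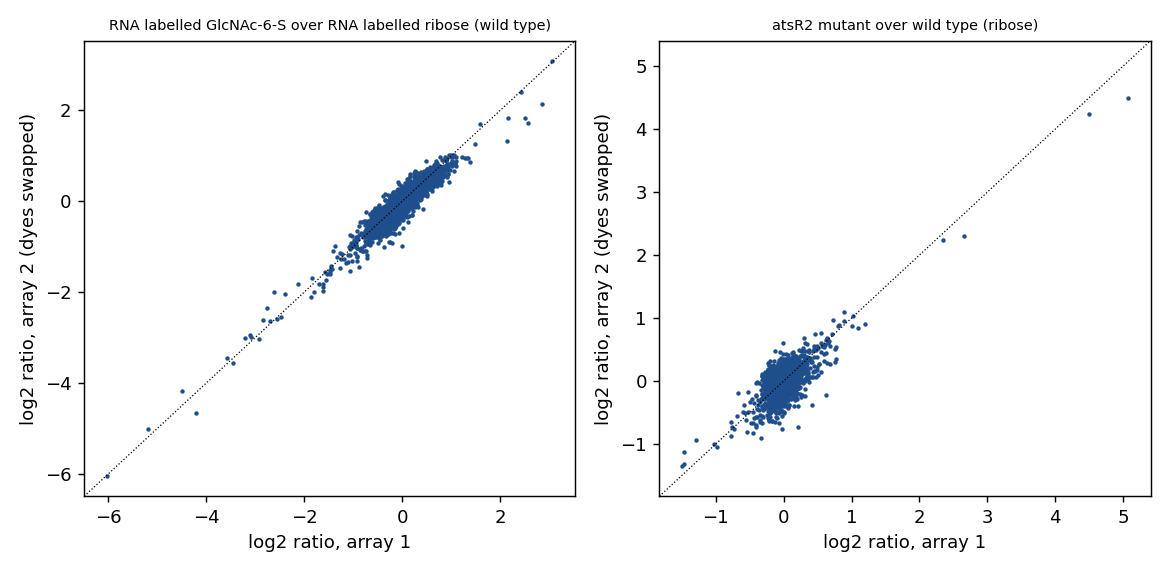
Log2 ratio of every tested feature on the 2 arrays of each comparison, turned so that a positive value means higher in the RNA labelled GlcNAc-6-S (left) or in the mutant (right); each point is 1 of 1859 features and the dotted line marks equality. The correlation was r = 0.950 in the first comparison and r = 0.779 in the second. The median absolute difference between the arrays was alike, at 0.118 and 0.114. The log2 ratios ranged less widely in the second, with an SD across features of 0.26 against 0.57.

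The first comparison asked which genes change when the wild type grows on GlcNAc-6-S in place of ribose. The largest difference was at Bbr_0851, whose log2 ratio of the RNA labelled GlcNAc-6-S over the RNA labelled ribose was -6.03 ± 0.01 (SD, n = 2), a 65.5-fold lower level (limma adjusted p = 3.6e-16). This direction follows from the dyes in the labels and opposes that of the study, which is known for genes switched on by the sulfated sugar; every direction below for this comparison is that of the labels. On the log2 scale, after scaling across arrays, the level of Bbr_0851 was 7.09 in the RNA labelled GlcNAc-6-S and 13.13 in the RNA labelled ribose, but 7.26 in the wild type on ribose of the second comparison, which lay on another slide. Bbr_0852, the next tag, followed at -5.11 ± 0.13 (SD, n = 2), or 34.4-fold lower (limma adjusted p = 3.6e-16). In the other direction, Bbr_1418 was 8.43-fold higher in the RNA labelled GlcNAc-6-S, with a log2 ratio of 3.08 ± 0.01 (SD, n = 2; limma adjusted p = 3.1e-14), and Bbr_1416 was 5.62-fold higher, with 2.49 ± 0.51 (SD, n = 2; limma adjusted p = 9.7e-11). Each of these 4 genes had the same direction in all of its measured probes, while the same direction on both arrays was a condition for naming it.

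At the study's threshold 34 genes had changed in this comparison, 26 of them lower and 8 higher in the RNA labelled GlcNAc-6-S. In all 34 every measured probe had changed at least 2-fold in the gene's direction. They lay in 16 places along the numbering, and 3 of these places held 19 of the 34 tags. The changes of at least 2-fold, 76 genes with 58 lower and 18 higher, formed 5 runs of consecutive tags that held 26 tags, where 1000 permuted gene orders gave at most 2 runs (permutation p = 0.001, the smallest these orders can give). The longest run held 9 tags, among them Bbr_0851 and Bbr_0852, and was lower by 1.19 to 6.03 on the log2 scale. Another run of 6 tags was lower by 1.76 to 4.44, with a median of -2.62, and 2 runs of 3 tags had medians of -1.25 and -1.23. The only run that was higher held 5 tags, among them Bbr_1416 and Bbr_1418, with values from 1.65 to 3.08 and a median of 2.42.

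**Figure D2:**
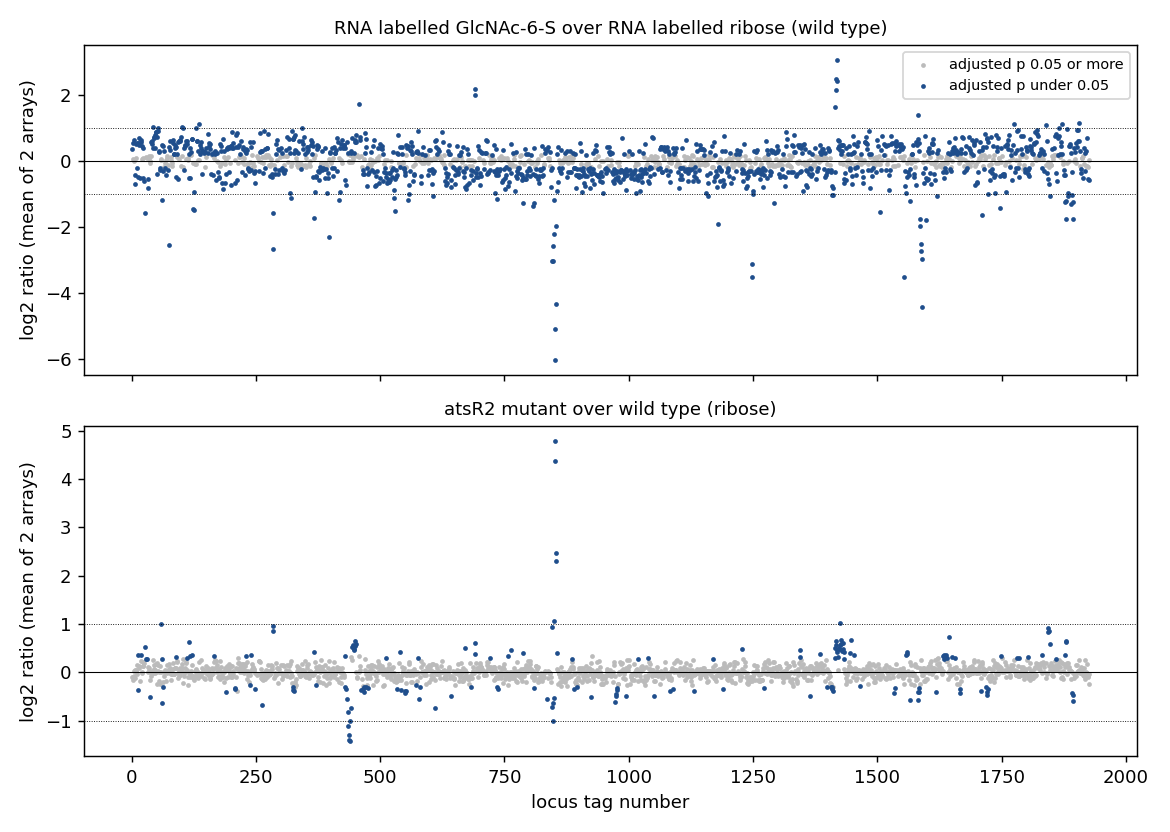
Log2 ratio of each tested locus tag (mean of 2 arrays) along the locus tag numbers, for the RNA labelled GlcNAc-6-S over the RNA labelled ribose (top) and for the atsR2 mutant over the wild type (bottom); blue points have an adjusted p under 0.05 and dotted lines mark 2-fold changes. The largest changes stand in narrow groups of neighbouring tags, and in the top panel the small changes lie higher at both ends of the numbering. The median over all tested tags in that panel was 0.14 in the first of 4 equal parts of the numbering and -0.15 in the next.

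At an adjusted p under the threshold, 1244 of 1859 features had changed, 609 higher and 635 lower, most of them by little: 809 differed by less than 1.41-fold. The direction of change followed the position of the gene in the numbering. Among changed locus tags of any size, with the numbering divided into 4 equal parts, 204 were higher and 104 lower in part 1, 102 were higher and 218 lower in part 2, 111 were higher and 190 lower in part 3, and 178 were higher and 121 lower in part 4. A cosine wave fitted to the 1762 tags that changed less than 2-fold had its peak at tag number 1919 of 1926, and the fitted values at peak and trough differed 1.25-fold (permutation p = 0.001, the smallest these orders can give). The 23 spike, plasmid and insertion element features, called blank features here because none was brighter than the brightest negative control in more than 1 of the 8 channels, had values from -0.75 to -0.01 with a median of -0.35, and 169 of the 1244 changes were larger than the largest of these. The count fell to 813 without array 1, to 812 without array 2 and to 582 with Agilent's processed signals.

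The tRNA features, a list chosen after the data were seen, were mostly higher in the RNA labelled GlcNAc-6-S. Of 20, 14 rose, 1 fell and 5 did not pass, both over all features and adjusted over the list alone. The values were 0.81 ± 0.13 (SD, n = 2) for tRNA-Asp, 0.73 ± 0.27 (SD, n = 2) for tRNA-Asn and 0.56 ± 0.06 (SD, n = 2) for tRNA-Tyr, while tRNA-Glu fell to -0.36 ± 0.01 (SD, n = 2). The list's median was 0.38, and camera with a preset correlation of 0.01 gave p = 7.8e-04, adjusted p = 0.0016 over the 2 comparisons. That call was lost with an estimated correlation (p = 0.33), and fry gave p = 0.032, adjusted p = 0.064. The median stayed positive, between 0.28 and 0.59, under every background correction and scaling tried, and the number that rose was 7 with Agilent's processed signals and 9 without array 1 or with the series matrix.

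**Figure D3:**
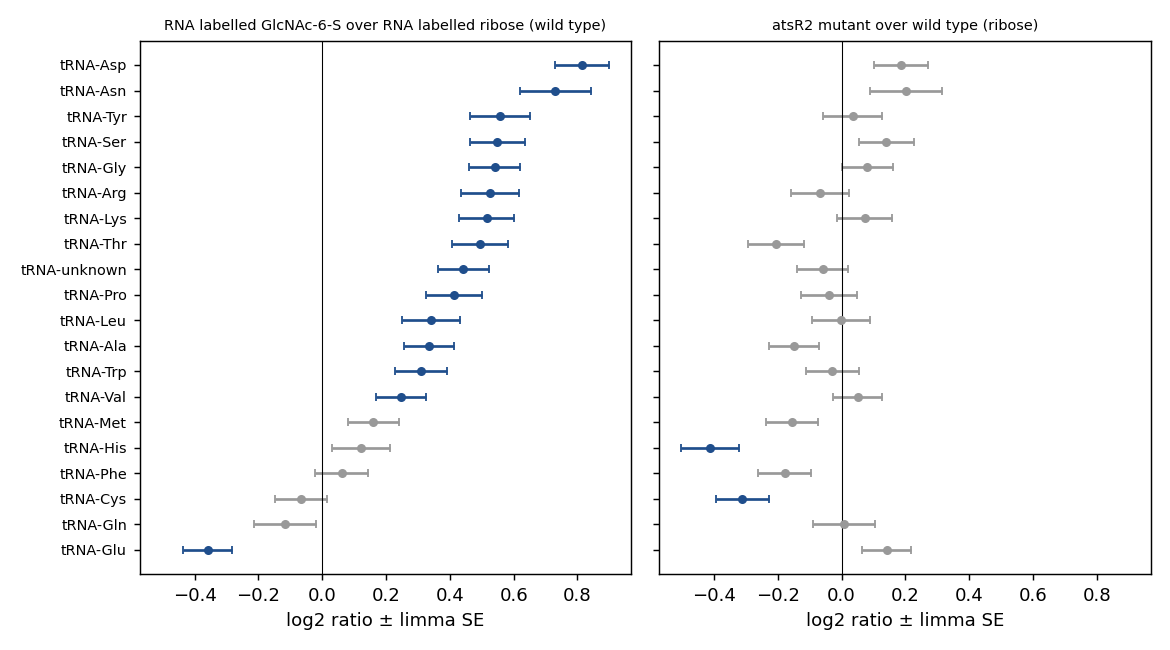
Log2 ratio of each tRNA feature (points, mean of 2 arrays; bars, limma standard error) in the first comparison (left) and in the mutant comparison (right); blue points have an adjusted p under 0.05. On the left 14 of 20 features lie above 0 and pass, and on the right 2 features pass, both below 0.

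The second comparison asked which genes respond to the loss of the regulator atsR2 when no sulfated sugar is supplied. The signal of atsR2 itself cannot be given, because its locus tag is not given in the sources used here. The mutant had far higher levels of the same neighbouring genes, Bbr_0851 and Bbr_0852. Bbr_0851 had a log2 ratio of mutant over wild type of 4.79 ± 0.41 (SD, n = 2; limma adjusted p = 1.2e-14), and because it was not well above background in the wild type on either array, it was at least 23.8-fold higher. Bbr_0852 was 20.6-fold higher, with 4.37 ± 0.19 (SD, n = 2; limma adjusted p = 4.8e-15), and its probes ranged from 3.63 to 4.87. In the mutant Bbr_0439 was lower, at -1.43 ± 0.10 (SD, n = 2; limma adjusted p = 5.5e-09), and Bbr_0437 at -1.40 ± 0.11 (SD, n = 2; limma adjusted p = 2.6e-08). Bbr_1418 and Bbr_1416 were also higher in the mutant, at 0.43 (limma adjusted p = 0.0020) and 0.65 (limma adjusted p = 0.0020). Neither Bbr_0439 nor Bbr_0437 was well above background in the mutant, which puts them at least 2.35-fold and 2.63-fold lower. Bbr_0437 lost its call with the series matrix values, with -3.08 and adjusted p = 0.073.

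At the study's threshold 4 genes had changed in the mutant, all of them higher and all consecutive, from Bbr_0851 on. The count of 4 was 10 with a normexp offset of 0, 4 higher and 6 lower. It was 17 with Agilent's processed signals, 6 higher and 11 lower, and 9 with the series matrix, 5 higher and 4 lower. That no gene passed as lower in the main fit thus depends on the processing. The 12 genes changed at least 2-fold held 2 runs of consecutive tags, 5 tags higher around Bbr_0851 and 5 tags lower around Bbr_0439, where 1000 permuted gene orders gave 0 runs (permutation p = 0.001, the smallest these orders can give). At an adjusted p under the threshold 190 of 1859 features had changed, 99 higher and 91 lower, and 131 of them by less than 1.41-fold. The blank features lay between -0.40 and -0.08 here, and 93 of the 190 changes were larger than the largest of these. Of the 20 tRNA features 0 were higher and 2 were lower in the mutant by limma and by Cyber-T alike, with 1 higher by limma at an unadjusted p under 0.05; the lower ones were tRNA-His at -0.41 ± 0.25 (SD, n = 2) and tRNA-Cys at -0.31 ± 0.14 (SD, n = 2). The count of 190 was 95 without array 2, 84 with Agilent's processed signals, 9 with the series matrix and 295 with a dye term.

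Around Bbr_0851 the comparisons differed from tag to tag. The 4 consecutive tags that end 2 before it were lower in the RNA labelled GlcNAc-6-S, with values from -3.04 to -2.21. In the mutant the first 3 of them were lower too, with fitted values from -1.02 to -0.63, but 2 of these were not well above background in the mutant, and the last of the 4 was not well above background in either RNA, so no change is given for it. The tag just before it, Bbr_0851 itself and the 3 tags after it were lower in the RNA labelled GlcNAc-6-S, from -6.03 to -1.19, and higher in the mutant, with fitted values from 1.05 to 4.79, although Bbr_0851 and the tag before it were not well above background in the wild type. For Bbr_0851 the difference between the comparisons passed (limma contrast, adjusted p = 9.7e-18), with no exact size, since the gene was not well above background in the wild type of the second comparison. With the sign of the first comparison turned, both changes of Bbr_0851 would run the same way, and whether they differ cannot be read from a bounded value. The tag 6 before Bbr_0851 was 0.94 higher in the mutant and at -0.21 in the other comparison. Bbr_0439 and Bbr_0437, lower in the mutant, had values of -0.04 and 0.02 in the first comparison (limma adjusted p = 0.70 and 0.88), and the difference itself passed for both (limma contrast, adjusted p = 1.4e-07 and 3.8e-07), again with no exact size because their values in the mutant are bounds.

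**Figure D4:**
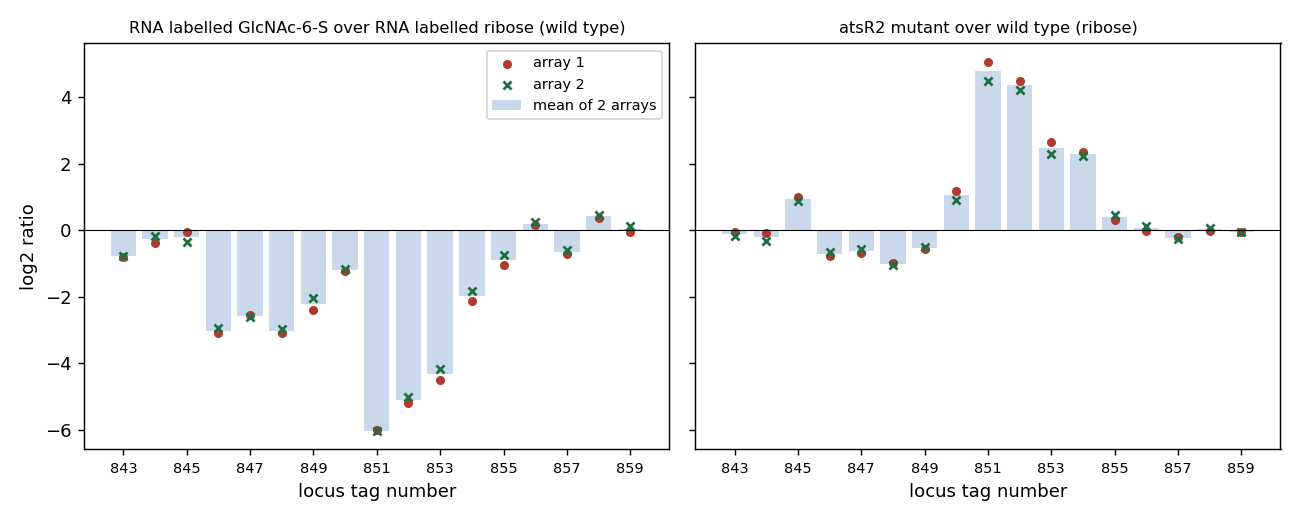
Log2 ratio of 17 neighbouring locus tags centred on Bbr_0851 (bars, mean of 2 arrays; points, each array) in the first comparison (left) and in the mutant comparison (right). Bbr_0851 stands at -6.03 on the left and at 4.79 on the right, and the tags 2 to 5 before it lie below 0 in both panels, 3 of them without a signal well above background in the mutant.

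Of all features, 43 were higher in both and 44 lower in both, where independent lists of these sizes would share 32.4 and 31.1 (Fisher's exact test, adjusted p = 0.054 and 0.018 over 4 tests). In opposite directions there were 56 features, 21 higher in the first comparison and lower in the mutant, against 29.8 for independent lists, and 35 the other way round, against 33.8 (Fisher's exact test, adjusted p = 0.068 and 0.83). Fisher's test takes features as independent, but neighbouring tags correlated with r = 0.49 in the first comparison and 0.61 in the second. These values are over all tags, with the runs of large changes included. Among the 1670 tags below the largest blank value in the first comparison it was 0.24, freed of the trend with intensity. No such value was computed for the second. The p-values of Fisher's test may therefore be too small. All 23 blank features also lay below 0 in both comparisons by the labels. A shared technical shift was not tested as a source of the overlap. Turning the sign of the first comparison would exchange 87 and 56, and neither overlap in the same direction would then pass Fisher's test. Of the 6 features changed at least 2-fold in both, 5 had opposite directions by the labels and 1 the same direction, and a turned sign would exchange these too. All 4 genes past the study's threshold in the mutant were past it in the first comparison, and 19 of the 34 genes past it in the first had changed in the mutant. The log2 ratios of the comparisons correlated across genes with Pearson's r = -0.12 and Spearman's rho = 0.22, and Pearson's r was 0.15 without the 17 tags around Bbr_0851. Both comparisons have the wild type on ribose as control, and if its RNA was shared, unchanged groups gave a mean r of 0.50 in 100 simulated draws, with a covariance of 0.00358 against the observed -0.0172, and an overlap of at most 0 features. Turning the sign of the first comparison would also turn the sign of the observed correlations and covariance. The draws hold no real effects, so they do not settle whether part of the excess over independent lists came from a shared control. The difference between the comparisons passed for 858 features, among them all 34 past the study's threshold in the first comparison, and with the sign of the first comparison turned for 1051, again with all 34. The overlap of 87 fell to 25 without array 1 and 26 without array 2 of the first comparison and to 33 without array 2 of the second, and the 858 fell to 462 and 525 without array 1 and array 2 of the first comparison.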

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

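All tests below were chosen after the result was seen, except that on background shared by dim channels.

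The feature named only CDS, which was in no comparison, was brighter than the brightest negative control spot in each of the 8 channels, by a factor of at least 1.05, with a log2 ratio of -0.94 in the mutant comparison and -0.02 in the other.

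The direction of the GlcNAc-6-S comparison rests on the dyes in the labels, and the levels in the wild type on ribose of the mutant comparison bear on it in opposite ways. Of the 34 genes past the study's threshold, that wild type lay closer to the RNA labelled GlcNAc-6-S for 29, or 85.3%, and closer to the RNA labelled ribose for 14.7%, with median gaps of 0.64 and 2.98 on the log2 scale; neighbouring genes are not independent, and by place along the numbering it was 12 of 16, while among the 76 genes changed at least 2-fold it was 46. Among the 1168 genes that changed less than 2-fold the share closer to the RNA labelled GlcNAc-6-S was 23.6%, and the wave along the tags had an amplitude of 0.02 against the RNA labelled ribose and 0.18 against the RNA labelled GlcNAc-6-S. Background shared by the dim channels could draw the ribose RNAs together and stays open. The share was 30.9% among the brightest of 4 groups of genes, with an upper 95% limit of 36.7%. That limit does not stay under the 35% set beforehand. With Agilent's processed signals, a condition added after the result was seen, the share was 21.1% with an upper limit of 26.4%. Both limits are binomial and take genes as independent, so they may be too low and measure no spread between arrays or cultures. Dyes recorded in reverse and lower transcription on GlcNAc-6-S cannot be told apart here, because the comparisons lie on separate slides and the labels do not say whether their ribose RNAs share a culture.

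The small changes of the GlcNAc-6-S comparison followed the locus tag numbers, with wave amplitudes of 0.18 and 0.14 on the swapped arrays, 0.16 on their mean, and from 0.12 with no background correction to 0.25 with Agilent's processed signals. In the mutant comparison the amplitude was 0.04, where permuted orders gave at most 0.036 (permutation p = 0.001, the smallest they can give). Neighbours among the 1670 tags below the largest blank value correlated with r = 0.24 after removal of the trend with intensity. The value was r = 0.17 after removal of the position trend too, a step added once the first value was seen. Permuted orders gave at most 0.11 for the latter. Background that differs at random from probe to probe would not be shared in this way, so it does not account for all small changes. With the position trend removed, however, the value cannot say what made the wave. Whether neighbouring genes share probe background was not tested. Genomic DNA in the labelled material would weigh most on dim genes, but the amplitude in the brightest of 4 groups of genes was 104.2% of that in the dimmest. A further hypothesis that stays open is gene copy number, which may be higher near the origin of replication in growing cells. It was not tested, since growth rates and DNA were not analysed here.

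The tRNA features were higher in the RNA labelled GlcNAc-6-S, with a median of 0.38. This lay at percentile 99.9 of 10000 lists of locus tags matched on brightness, so a shift of this size was not general among locus tags of like brightness. Each matched list was drawn gene by gene, while tRNA features may vary together. The tRNA list was also chosen after the data were seen, so the percentile may be too high. Members that vary together between arrays stay open as an explanation of the camera result, which was lost at an estimated correlation of 0.38 (p = 0.33); that estimate rests on 2 residual degrees of freedom. An unequal yield of small RNA between the preparations and an effect of the sugar were not tested apart.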

How the results depend on the processing

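Counts larger than the blank shifts, the turned sign, and the alternatives for the tRNA features and for the difference between the comparisons were chosen after the data were seen. All 8 values of the named genes kept their direction under the 15 alternatives set before the data were examined, and 119 of the 120 values their side of the threshold; the exception is Bbr_0437 with the series matrix. The number of genes past the study's threshold in the GlcNAc-6-S comparison lay between 30 and 45. In the mutant comparison that number was 10 with a normexp offset of 0, 17 with Agilent's processed signals and 9 with the series matrix, and 4 otherwise; the share higher was 40%, 35.3% and 55.6% under these in place of 100%. With Agilent's processed signals, 582 genes changed on GlcNAc-6-S, 84 in the mutant, 24 the same way in both, and 183 differed between the comparisons. With the series matrix, 9 changed in the mutant, 312 differed and 0 changed the same way in both by limma, against 159 at an unadjusted p under 0.05; 29 features had no spread there. A dye term gave 295 in the mutant and 147 the same way, fitting each comparison alone 75 and 32, and the fit per probe 116 and 48. Leaving out an array gave 812 to 813 genes on GlcNAc-6-S, 95 to 177 in the mutant, 25 to 108 the same way and 462 to 810 differing; these fits have fewer arrays, and the lone array is assumed to vary like the others. Counting only changes larger than the largest blank shift left 169 on GlcNAc-6-S and 93 in the mutant. The turned sign gave 56 the same way, 62.5% of them higher, and 1051 differing. Of the genes changed in the mutant, 52.1% were higher, against 32.1% with Agilent's processed signals, 64.5% with median centring, 77.8% with the series matrix, and 40.1% and 65.3% without array 1 or 2 of that comparison; of those changed the same way, 49.4% were higher, against 20.8% with Agilent's processed signals and 60.3% with median centring, and 36.1% and 66.7% without array 1 or 2 of the mutant comparison. Among genes changed the same way the share higher was also 62.9% with a normexp offset of 0 and 62.5% with each comparison fitted alone. Beyond the smaller number of arrays, the cause of these shifts was not tested. Aquantile scaling alters no ratio within an array, and the dye term, each comparison fitted alone and Cyber-T left the log2 ratios of the named genes unchanged. The direction of a named gene could not turn under these alternatives. Nor could it turn when an array was left out, since the named genes had been chosen for the same sign on both arrays. The slide as a block was not run, because each slide holds 1 comparison and no correlation could be estimated, and the alternatives for gene lists were not run, because no list had members. Between 36.6% and 74.8% of spots per channel were well above background in the mutant comparison, which limits the folds of genes near background; leaving out dim probes gave 178 changed genes there.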

Other observations

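The values here were chosen after the data were seen. The 16S rRNA feature was not well above background in either RNA of the GlcNAc-6-S comparison, so no change is given for it there, and it had a log2 ratio of 0.20 ± 0.60 (SD, n = 2; limma adjusted p = 0.44) in the mutant over the wild type. The 67 tested features dimmer than the brightest blank feature had a median log2 ratio of 0.09 in the first comparison, with quartiles of -0.13 and 0.20, where the blank features had a median of -0.35. A stricter definition, as dim as the median blank feature, was tried first and held 1 feature, at 0.11.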
